A study of Bubalus bubalis with 6 samples.

How the data were processed

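Polyadenylated RNA from buffalo (Bubalus bubalis) intramuscular adipocytes was sequenced on a DNBSEQ platform in 6 samples. Per the labels, 3 samples had received an adenovirus that carries EGFP (a green fluorescent protein, the control) and 3 an adenovirus that carries lncFABP4, a long non-coding RNA. The cells were kept with the virus for 48 hours and then in inducing medium for 48 hours, and were collected on day 4. The labels speak of wells plated in triplicate and do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

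The deposited table holds 1 value per gene model and sample for 19476 models above 0 in at least 1 sample. The values were read as FPKM (fragments scaled to the length of the model and to the mapped fragments of the sample): the table names no unit in its header, and the deposited values are decimals whose column totals differ between samples, from 340165 to 360920. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. Each model has an identifier and, in most cases, a gene name taken by the authors from a protein match. Of the 19476 models, 4570 had no gene name, and 13563 different names were found. Several models can share a name, and near-identical genes can share reads. Every column of values in the table was used.

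The number of reads behind each value is unknown. Models under 0.3 FPKM in every sample share steps of a single read, which gave a depth relative to EGFP replicate 1 of 1.01 and 0.981 for EGFP replicates 2 and 3, and of 0.954, 0.941 and 0.925 for lncFABP4 replicates 1, 2 and 3. Between 2.32% and 3.18% of the low models lay within 0.01 (log2) of that step, against 0.617% to 0.820% in an average window of that width. These are estimates of relative depth only.

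Models of at least 1 FPKM in at least 3 of the 6 samples were kept, 11064 in all, of which 878 had no name. The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided, on log2(FPKM + 1), lncFABP4 minus EGFP, without a replicate block and with Benjamini-Hochberg adjustment over the 11064 models at a threshold of 0.05. A change on this scale understates the change of low genes. Values are given as mean ± SD of 3 samples and changes as log2 with the standard error (SE).

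There were 23 gene lists with 500 genes, of which 394 were matched by name and 309 tested. Models with a protein entry but no gene name were not matched, among them models whose entries are those of SCD and DDX58, so these genes are absent from the counts of the fatty acid synthesis, PPAR signalling and interferon lists. Lists with at least 5 tested models were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 18 lists. Every model that carries a member's name entered the list, and the counts per list are counts of models. The design did not say how models that share a name were to be treated. After a first run of the list tests had been seen, a form that used only the most abundant model of each name, with a variance trend in camera, was used for a time; it called 1 list more, that of pericyte and smooth muscle markers. The form of the first run, which follows the written design most closely, is the main one, and the others are alternatives.

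The samples, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and the 10 largest falls among models with an adjusted p under 0.05, groups that do not overlap, a mean of at least 5 FPKM in the higher group and a gene name. It adds up to 4 members of each list with the smallest adjusted p under 0.05, and always FABP4, PPARG, CEBPA, ADIPOQ and LPL. Up to 2 unnamed models per direction may be given. Some genes that the rule takes are not reported here. Other members named beside a count of 5 or fewer, and the genes of the lists made afterwards, were chosen after their values were seen.

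Alternatives were other pseudocounts (0.1 and 0.01), no filter, a filter at 5 FPKM, TMM, quantile and median-of-ratios scaling, the replicate number as a block, each sample and each replicate number left out, a robust variance model (with statmod 1.5.0), sample weights and a fold of at least 2. TMM factors were computed in base R without weights, because the values are not counts. Summing models per gene name, rescaling without FABP4, the other forms of the list test and the lists without FABP4 were added after the data had been seen. Alternatives that need counts were not run. The gene test was tested on simulated data built from the spread of the 11064 models. It recovered 44% of 50 models changed by 1.5-fold, 84% of 50 changed by 2-fold, and 98% of 50 at both 4-fold and 8-fold, with 15 false calls among the unchanged models. The simulation changed 200 models in all, against 2958 called in the data, so these shares need not hold for the data.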

Results

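Transcript abundance was measured in cultured cells that the labels call intramuscular adipocytes of buffalo, after transduction with an adenovirus for lncFABP4 or for EGFP. Adipocytes are fat-storing cells, and intramuscular ones lie between muscle fibres. The fat cell genes CEBPA and ADIPOQ reached at most 0.190 and 0.0559 FPKM in any sample, although FABP4 and PPARG were well above 1 FPKM. Whether the cells were mature is therefore not known. There were 3 samples per group, all from day 4. Column totals ranged from 340165 to 360920 FPKM, and 10907 to 10987 gene models per sample reached 1 FPKM. The question was which genes differ in abundance when lncFABP4 is overexpressed during adipogenic differentiation.

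FABP4, which encodes the fatty acid binding protein of adipocytes and gives the long non-coding RNA its name, was 58.1-fold higher after lncFABP4 transduction. It stood at 167 ± 26.0 FPKM in the EGFP samples and 9699 ± 2855 FPKM in the lncFABP4 samples (SD, n = 3 each), a log2 change of 5.82 (SE 0.22, limma adjusted p = 9.79e-06). The 3 lncFABP4 samples held 6505, 10588 and 12003 FPKM, and the EGFP samples 154, 149 and 197 FPKM. The FABP4 model alone took 1.80%, 3.03% and 3.41% of the total in the lncFABP4 samples and 0.0437% to 0.0557% in the EGFP samples. No model of the table is named as lncFABP4, so its own level is not reported, and the table does not tell whether reads of the transduced RNA were counted on the FABP4 model.

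PPARG, the main transcription factor of fat cell formation, rose from 12.2 ± 0.527 to 25.2 ± 1.77 FPKM (SD, n = 3), a log2 change of 0.98 (SE 0.08, limma adjusted p = 0.000321). LPL, the lipase that releases fatty acids from circulating triglyceride, fell from 2.78 ± 0.710 to 0.999 ± 0.160 FPKM (log2 change -0.90, SE 0.14, limma adjusted p = 0.00349). CEBPA and ADIPOQ, a partner of PPARG and the gene of adiponectin, were under the minimum for testing. CEBPA was listed at 0.153, 0.186 and 0.174 FPKM in the EGFP samples and 0.111, 0.128 and 0.190 FPKM in the lncFABP4 samples. ADIPOQ was listed at 0.0258, 0 and 0.0397 FPKM in the former and 0, 0 and 0.0559 FPKM in the latter.

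**Figure D1:**
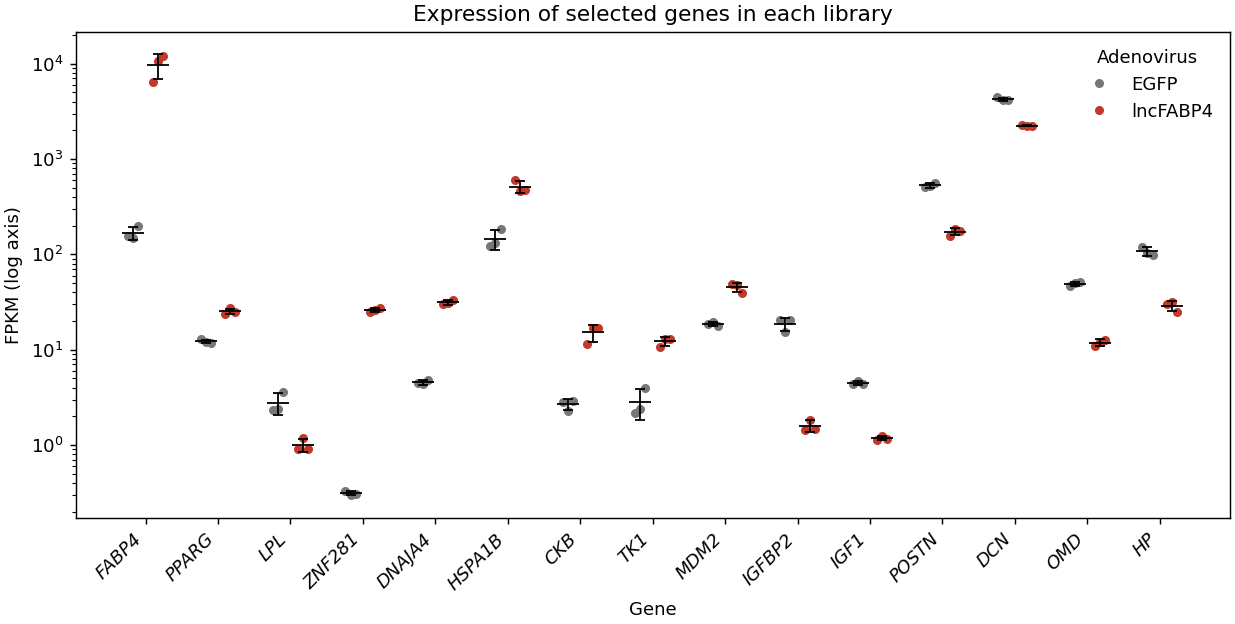
FPKM of 15 genes on a log axis. Each point is 1 library, grey for EGFP and red for lncFABP4, and the black bars are the mean and SD of 3 libraries; FABP4 lies between 6505 and 12003 FPKM in the lncFABP4 libraries and at 197 FPKM or less in the EGFP libraries.

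Across all genes, ZNF281, a zinc finger transcription factor, had the largest rise after FABP4 on the log2(FPKM + 1) scale, and by fold its rise was larger than that of FABP4. It went from 0.313 ± 0.0170 to 26.0 ± 1.29 FPKM (SD, n = 3), 83.2-fold, with a log2 change of 4.36 (SE 0.08, limma adjusted p = 1.30e-07). The table does not tell whether reads from the vector were counted on this model. DNAJA4, a co-chaperone, rose from 4.53 to 31.4 FPKM (log2 2.55), and the stress-inducible chaperones HSPA1B and HSPA1A rose 3.50-fold and 3.47-fold, although these near-identical copies can share reads. The brain-type creatine kinase gene CKB rose by 2.12, the mitochondrial carrier SLC25A35 by 1.81, the thymidine kinase TK1 by 1.81, PSPH of serine synthesis by 1.79 and the protease inhibitor SERPINB2 by 1.75 (log2). The largest fall was that of IGFBP2, a binding protein of insulin-like growth factors, from 18.8 ± 2.98 to 1.59 ± 0.229 FPKM (log2 change -2.93, SE 0.13, limma adjusted p = 2.22e-05). The cell adhesion gene NRCAM (log2 -2.20), the keratan sulfate proteoglycan OMD (-1.96), the growth factor PDGFC (-1.81), the retinal reductase DHRS3 (-1.79) and the elongation factor EEF1A2 (-1.76) also fell. So did genes of the acute-phase and complement response: both models of SAA1 (log2 -2.06 and -1.68, which can share reads), HP (-1.86) and C1R (-1.68). Without replicate number 3 of both groups, DHRS3 was no longer called. Among models without a name, evm.model.chr6.393 rose by 1.23 and evm.model.chr7.213 was changed by -2.04 (log2). The latter is next in number to the NRCAM model, evm.model.chr7.214, and had like values (9.18 to 1.47 FPKM, against 11.1 to 1.61 FPKM for NRCAM). Whether they are separate genes is not known.

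Of 11064 models tested, 2958 passed limma at an adjusted p of 0.05, 1827 higher and 1131 lower after lncFABP4 transduction, so 61.8% of the calls were higher. Scaling moved that split: 51.2% were higher with TMM factors (1466 against 1397 lower), 50.8% with quantile scaling (1461 against 1413) and 49.2% with median-of-ratios factors (1414 against 1458). Most changes were small, with a median size of 0.46 (log2) among the called models, and 157 reached a fold of 2, 68 higher and 89 lower. The groups did not overlap in 43.9% of the models, against 10% by chance. Pearson's r across genes, which are not independent replicates, was 0.988 to 0.991 between EGFP samples, 0.986 to 0.993 between lncFABP4 samples and 0.966 to 0.977 between the groups. Without replicate number 3 of both groups, 567 models were called, and without number 2, 1406.

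**Figure D2:**
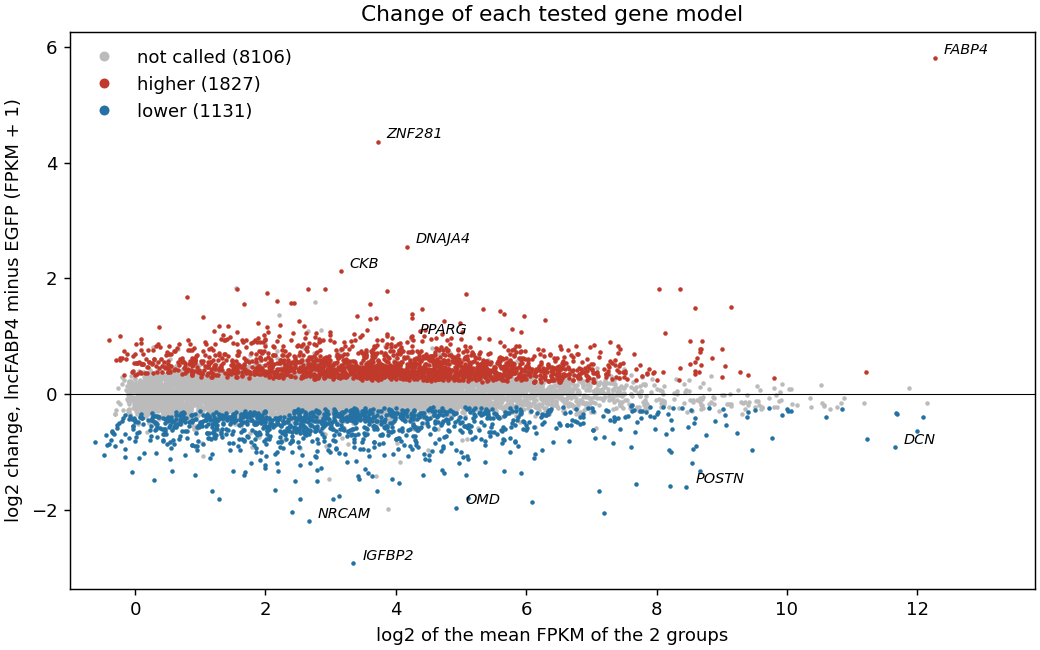
Change of each of 11064 gene models (log2 of lncFABP4 minus EGFP, on FPKM + 1) against the log2 of its mean FPKM. Red marks 1827 models called higher and blue 1131 called lower at an adjusted p of 0.05 (limma), grey the others; FABP4 at 5.82 and ZNF281 at 4.36 stand above the rest. The share called higher was 49.2% to 51.2% under 3 other scalings.

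In the main camera setting, extracellular matrix genes were the list with the smallest adjusted p. That did not hold in several settings, among them no filter, quantile scaling, sample weights and an estimated correlation. It also did not hold without lncFABP4 replicate 1 or without replicate 1 of both groups. With sample weights and without these samples, cell cycle genes had the smallest adjusted p (camera of limma, 4.23e-06 against 0.000521 without lncFABP4 replicate 1). Both lists had the same adjusted p with the other pseudocounts, TMM or median-of-ratios factors or a replicate block. Of the 31 models of the matrix list, 13 fell, 3 rose and 15 were not called, and 14 fell and 3 rose when adjusted over the list alone (median log2 -0.28, camera of limma adjusted p = 0.000220, adjusted p = 0.268 with an estimated correlation). With quantile scaling the median was -0.13, with 11 lower and 2 higher (camera adjusted p = 0.0127). Fewer were lower without lncFABP4 replicate 2 or 3 (8 each) and without EGFP replicate 1 or without a filter on low values (9 each). POSTN, the matrix protein periostin, fell from 529 ± 27.7 to 174 ± 14.7 FPKM (log2 -1.60), and the proteoglycan DCN from 4235 ± 177 to 2230 ± 29.3 FPKM (-0.92). The fibrillar collagen gene COL3A1 (log2 -0.77) and LOX, which cross-links collagen (-0.84), fell too. The 3 members that rose were the collagenase MMP1 (log2 1.13), COL15A1 (0.41) and COL6A3 (0.35), named after their values were seen. Only the call of MMP1 was kept throughout. Leaving out a single library ended that of COL15A1 for 5 of the 6 libraries (limma adjusted p from 0.0538 to 0.144) and that of COL6A3 for 3 (0.0782 to 0.0967), and TMM and median-of-ratios scaling ended both.

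In the insulin and glucose list, 7 of 20 models fell, 3 rose and 10 were not called, with 8 falling and 3 rising adjusted over the list alone (median log2 -0.20, camera of limma adjusted p = 0.00113, adjusted p = 0.146 with an estimated correlation). IGF1, an insulin-like growth factor, fell from 4.48 to 1.18 FPKM (log2 -1.33), and IGFBP5, another of its binding proteins, from 308 to 103 FPKM (-1.56). PFKFB3, a regulator of glycolysis, fell by 0.62. The 3 models that rose were both models of LDHA (log2 0.38 and 0.30) and one of IRS1 (0.35). Leaving out a single library ended the calls of IRS1 and of the less abundant LDHA model for 4 of the 6 libraries (limma adjusted p from 0.0541 to 0.113 and from 0.0724 to 0.0979). Median-of-ratios scaling ended both as well, and without a filter on low values IRS1 and the more abundant LDHA model were not called.

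Mature adipocyte and lipid droplet genes rose in 9 of 16 models, fell in 2 and were not called in 5, with the same numbers adjusted over the list alone (median log2 0.37, camera of limma adjusted p = 0.00888, adjusted p = 0.268 with an estimated correlation). With FABP4 left out of the list, the adjusted p of camera was 0.0460. G0S2, an inhibitor of triglyceride breakdown, rose from 10.2 ± 1.49 to 28.0 ± 4.11 FPKM (log2 1.38), and the caveolin gene CAV1 rose by 0.74. The 2 models that fell were LPL and BSCL2, the seipin gene (log2 -0.47). The call of BSCL2 was lost without a filter on low values and when any of 4 of the 6 libraries was left out (limma adjusted p from 0.0895 to 0.101 for the libraries).

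p53 targets rose in 10 of 18 models, with 1 lower and 7 not called, and 11 rose and 2 fell adjusted over the list alone (median log2 0.37, camera of limma adjusted p = 0.000983, adjusted p = 0.146 with an estimated correlation). MDM2, the ubiquitin ligase of p53, rose from 18.6 ± 0.940 to 45.1 ± 5.18 FPKM (log2 1.23). GDF15, a stress-induced cytokine, rose by 1.34, PLK2 by 0.95 and the nuclease AEN by 0.92. The model that fell was 1 of 2 named CCNG1 (log2 -0.70), a call lost without a filter on low values and when any of 3 of the 6 libraries was left out (limma adjusted p from 0.0625 to 0.102 for the libraries). Cell cycle genes rose in 12 of 23 models, with 0 lower and 11 not called, and 13 rose adjusted over the list alone (median log2 0.49, camera of limma adjusted p = 0.000383, adjusted p = 0.410 with an estimated correlation). TYMS of thymidylate synthesis rose from 84.4 to 137 FPKM (log2 0.69), the replication licensing genes MCM2 and MCM6 by 0.94 and 0.77, and the cyclin CCNE2 by 1.06. With a filter at 5 FPKM, which leaves out low models, this list was not called (camera adjusted p = 0.264), with 3 models higher and a median log2 of 0.21. In the same list 6 models were higher without replicate number 2 of both groups. Without replicate number 3 of both groups, fewer models were called in all 5 lists: 6 lower in the matrix list, 3 lower in the insulin list, 3 higher in the adipocyte list, 6 higher among p53 targets and 2 higher in the cell cycle list.

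**Figure D3:**
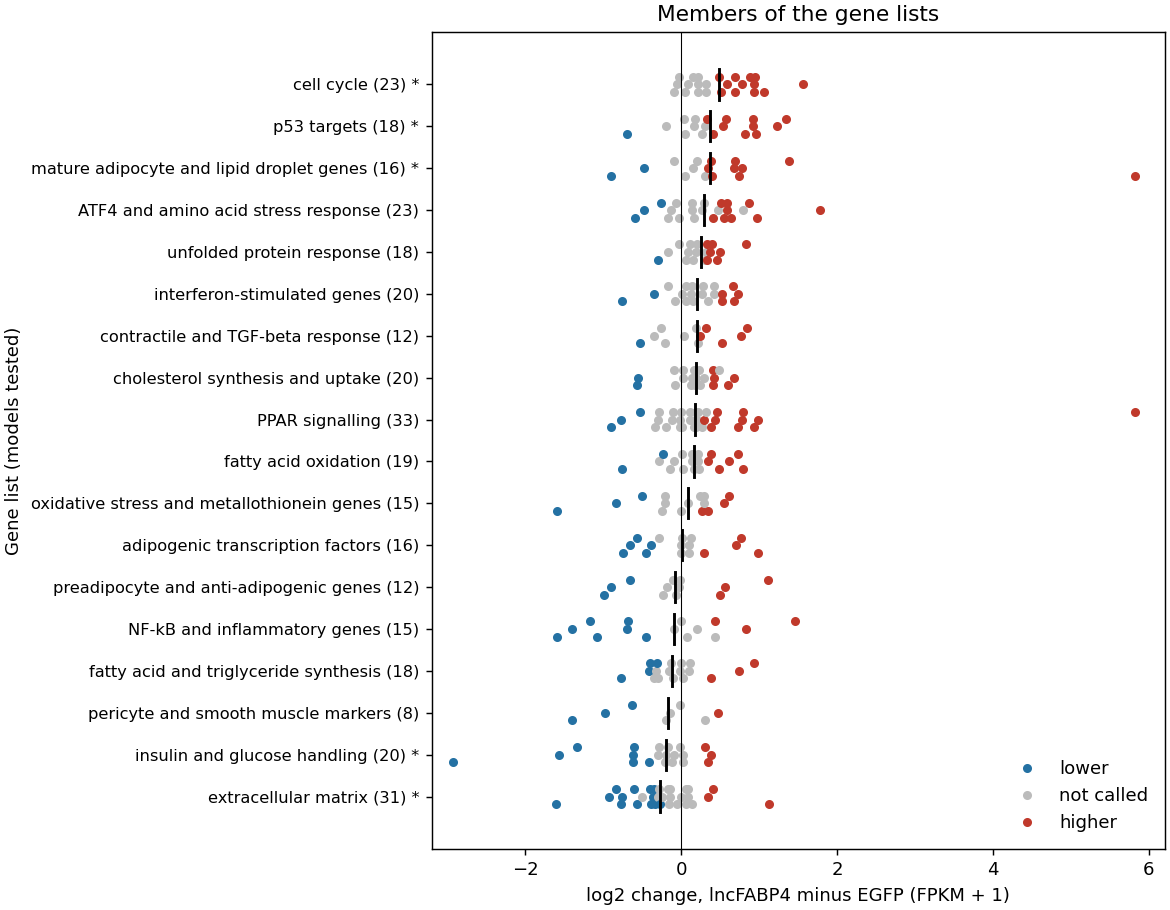
Log2 change (lncFABP4 minus EGFP, on FPKM + 1) of the tested models of 18 gene lists, with the number of models in brackets. Points are models, red called higher, blue called lower and grey not called (limma), black bars are list medians, and an asterisk marks the 5 lists called by camera, of which 0 were called with an estimated correlation.

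Lists of lipid metabolism and of transcription factors were not called by camera, with members moving both ways. Adipogenic transcription factors had 4 of 16 models higher, 5 lower and 7 not called (4 and 6 adjusted over the list alone), with KLF4 rising by 0.76 and ZBTB16 and KLF9 changed by -0.66 and -0.56 (log2). The median of this list was 0.01 and its camera direction was down (limma adjusted p = 0.565). PPAR signalling had 10 of 33 higher and 3 lower (12 and 6 adjusted over the list alone, limma camera adjusted p = 0.190), with CPT1A, the carnitine transferase of fatty acid oxidation, rising by 0.73 and FABP3 by 0.93. Fatty acid oxidation had 6 of 19 higher and 2 lower (8 and 3 over the list alone, limma camera adjusted p = 0.246). ACADVL rose by 0.61 and ETFB by 0.48, and PDK4, a kinase that restrains glucose oxidation, was changed by -0.76. Fatty acid and triglyceride synthesis had 3 of 18 higher and 4 lower (3 and 5 over the list alone, limma camera adjusted p = 0.196). GPAT3, DGAT2 and ACACA rose by 0.74, 0.94 and 0.38, and the desaturase FADS2 was changed by -0.77. ACACA was not called without lncFABP4 replicate 2 (limma adjusted p = 0.0507). Cholesterol synthesis and uptake had 5 of 20 higher and 2 lower, likewise adjusted over the list alone (limma camera adjusted p = 0.196). FDPS rose by 0.67, and SC5D was changed by -0.57 in its more abundant model. Preadipocyte and anti-adipogenic genes had 3 of 12 higher and 3 lower, also over the list alone (limma camera adjusted p = 0.320). WNT5A rose by 1.11 and KLF2 by 0.56, and DPP4 and THY1 were changed by -0.90 and -0.66. Leaving out a single library gave 1 to 5 models lower in the fatty acid and triglyceride synthesis list, 3 to 7 higher in the cholesterol list, 1 or 2 lower in the oxidation list and 3 to 5 lower in PPAR signalling. TMM and median-of-ratios factors each gave 10 higher and 6 lower in PPAR signalling. Without replicate 2 of both groups 1 model was higher in the cholesterol list. Without replicate 3 of both groups, 5 were higher in PPAR signalling, 3 in the oxidation list, 2 in the cholesterol list and 1 each in the synthesis and preadipocyte lists, and 1 was lower among the adipogenic transcription factors.

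Inflammatory and stress lists were not called by camera in the main setting either. Without a filter on low values the ATF4 and unfolded protein lists were both called (camera adjusted p = 0.00918 each), and so was each without some of the libraries. With an estimated correlation neither was called (camera adjusted p = 0.334 and 0.410). The ATF4 list was called without EGFP replicate 1 (adjusted p = 0.0456), EGFP replicate 3 (0.0447), lncFABP4 replicate 2 (0.0296) or replicate 3 of both groups (0.0344). The unfolded protein list was called without EGFP replicate 3 (0.0474), lncFABP4 replicate 1 (0.0293) or replicate 1 of both groups (0.0422). NF-kB and inflammatory genes had 3 of 15 models higher and 7 lower (4 and 7 adjusted over the list alone, limma camera adjusted p = 0.0941). CCL2, a monocyte chemokine, rose from 20.9 to 59.6 FPKM (log2 1.47), while SOD2, VCAM1 and C3 were changed by -1.59, -1.40 and -1.17. Genes of the ATF4 response had 9 of 23 higher and 3 lower (10 and 3 over the list alone, limma camera adjusted p = 0.0732). PSPH, ALDH1L2 (log2 0.88) and ASNS (0.59) rose and VLDLR fell (-0.48). The unfolded protein response had 7 of 18 higher and 1 lower, also over the list alone (limma camera adjusted p = 0.0658). MANF rose by 0.83, CALR by 0.50, DNAJB11 by 0.40 and HERPUD1 by 0.33, and the model that fell was DNAJB9 (-0.30). The call of DNAJB9 was lost without a filter on low values, after rescaling without FABP4 and when any of 5 of the 6 libraries was left out (limma adjusted p from 0.0550 to 0.138 for the libraries). Interferon-stimulated genes had 5 of 20 higher and 2 lower, also over the list alone (limma camera adjusted p = 0.246). ISG15 (log2 0.73), CMPK2 (0.52) and MX1 (0.53) rose and XAF1 fell (-0.76); these 4 calls were lost without a filter on low values and when at least 1 of the libraries was left out. Oxidative stress genes had 4 of 15 higher and 3 lower (5 and 3 over the list alone, limma camera adjusted p = 0.846), with SLC7A11 rising by 0.54 and NQO1 changed by -0.50. Its median was 0.09 while its mean was -0.06 and its camera direction down. The contractile and TGF-beta list had 5 of 12 higher and 1 lower (7 and 2 over the list alone, limma camera adjusted p = 0.478). CNN1, TPM2 and ACTA2 rose by 0.76, 0.52 and 0.85, and TGFBI was changed by -0.52. Leaving out a single library ended the calls of HERPUD1 and ACTA2 for 2 of the 6 libraries (limma adjusted p up to 0.0635 and 0.0638) and that of SLC7A11 without EGFP replicate 3 (0.0510). It also moved the models called higher to between 0 and 9 in the interferon list, to as few as 2 in the contractile and oxidative stress lists and to as few as 4 in the unfolded protein list. Without replicate 3 of both groups, 3 were higher in the ATF4 list, 1 each in the unfolded protein, oxidative stress and contractile lists and 0 in the interferon list, and 4 were lower in the inflammatory list.

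Markers of other cell types were mostly low. Pericyte and smooth muscle markers had 1 of 8 models higher and 3 lower, likewise over the list alone, and were not called (limma camera adjusted p = 0.0978). With only the most abundant model of each name, an alternative chosen after a first result had been seen, camera gave an adjusted p of 0.0276, against 0.334 for all models with an estimated correlation. KCNJ8 and ABCC9, which together form a potassium channel, fell from 48.8 to 18.4 FPKM (log2 -1.40) and from 10.7 to 4.92 FPKM (-0.97), DES fell by 0.63, and the lower of 2 CSPG4 models rose by 0.47. Skeletal muscle markers had 2 tested models, both lower, also adjusted over the list alone: DES and MYH3 (log2 -0.46). Of 2 endothelial models VWF rose (log2 0.34), and 2 were higher adjusted over the list alone. Of 4 leukocyte models CD14 rose from 10.6 to 27.5 FPKM (log2 1.31) and CD163 fell (-0.56), with 2 higher and 1 lower over the list alone. Leaving out a single library ended the calls of VWF and CSPG4 for 4 of the 6 libraries (limma adjusted p from 0.0642 to 0.0821 and from 0.0680 to 0.0842) and those of CD163 and MYH3 for 3 (0.0591 to 0.0647 and 0.0674 to 0.0738). The single Schwann cell model tested, ERBB3, was not called (log2 0.09), and 0 mitochondrially encoded genes were matched.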

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

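Summing models per gene name, rescaling without FABP4, the lists without FABP4 and the other forms of the list test were chosen after the results were seen. FABP4 kept its direction and its call in all alternatives run, at a log2 change of 5.33 with quantile scaling to 6.08 without lncFABP4 replicate 1. The count of 2958 called models (1827 higher, 1131 lower) was larger with sample weights (4982, of which 2941 higher and 2041 lower) and smaller with a fold of at least 2 (157, of which 68 higher and 89 lower). Leaving out samples gave 567 to 3468 calls, 335 to 2022 higher and 232 to 1446 lower. The count was 1948 without EGFP replicate 1, 1835 without EGFP replicate 3, 1815 without lncFABP4 replicate 2, 1673 without lncFABP4 replicate 3, 1406 without replicate 2 of both groups and 567 without replicate 3 of both; fewer samples were tested there, and no further cause was tested. Called models kept their sign in every setting that tested them, except 1 of 2835 with models summed per gene name. Every setting reuses the samples in which these models were called. Kept signs are thus close to fixed in advance and no independent support, also for the named models that follow. Of 2327 values of 112 called models named by the rule or afterwards, under 21 alternatives, 2173 kept direction and call, 154 kept the direction but missed the threshold and 0 reversed, and 40 of the 154 came without replicate 3 of both groups. Leaving out a single library ended 61 calls of 19 of these models, at adjusted p from 0.0501 to 0.144 (limma): 12, 5 and 13 without EGFP replicate 1, 2 and 3, and 1, 14 and 16 without lncFABP4 replicate 1, 2 and 3. These were ACACA, ACTA2, BSCL2, CCNG1, CD163, CMPK2, COL15A1, COL6A3, CSPG4, DNAJB9, HERPUD1, IRS1, ISG15, LDHA (1 model), MX1, MYH3, SLC7A11, VWF and XAF1. Camera called 5 lists, against 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 11 with fry, which asks another question. Fry called the same 5 lists and those of PPAR signalling, fatty acid oxidation, ATF4, unfolded protein, inflammatory and pericyte genes. In the insulin and p53 lists the correlations that camera estimated, -0.0296 and -0.0128, were below the preset 0.01. Their unadjusted camera p still rose, from 0.000251 to 0.0162 and from 0.000164 to 0.0151, so a higher correlation was not the cause there. The 2 forms of camera thus differ in more than the correlation. The estimates of the adipocyte, matrix and cell cycle lists were higher (0.0227, 0.0889 and 0.329). The loss of their calls need not come from the correlation alone either, and the cause was not tested. With the most abundant model per name camera called 6, with or without a variance trend. The 6th was the pericyte list, at an adjusted p of 0.0276 without that trend and 0.0288 with it, against 0.0645 to 0.334 over all other camera settings. For the sample structure, the median correlation between groups, 0.971, was 0.963 with a pseudocount of 0.1 and 0.987 without a filter; the cause was not tested. The labels do not say that the numbers pair the samples, so the main test had no replicate block. Same-numbered samples had correlations of their deviations of 0.18, 0.29 and -0.08. The 0.29, between the samples of number 2, was the highest of all pairs, while EGFP replicate 3 correlated best with lncFABP4 replicate 1 (0.20). These values do not settle whether the numbers pair the samples. With a replicate block 3336 models were called and 5 lists. The absolute depth is unknown, and at 3 samples per group simulated changes of 1.5-fold were recovered in 44% of models. That simulation changed 200 of 11064 models, against 2958 called in the data, so the 44% need not hold for these data.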

Other observations

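The heat-shock and acute-phase lists, the neighbours of FABP4 and ZNF281, the comparison with other adipocyte genes, the count without 1 library, the count of splits and the use of the interferon list were tests chosen after results were seen. Chaperone genes beyond those of the report were higher after lncFABP4 transduction. A list of heat-shock factor targets was made after HSPA1A, HSPA1B, DNAJA4, BAG3, HSPA4L and CACYBP had been seen to rise. Of the 22 tested models of its other members, 16 were higher, 0 lower and 6 not called, with a median log2 change of 0.45 (camera of limma p = 2.69e-08, p = 0.0803 with an estimated correlation). DNAJB1 rose from 20.6 ± 2.39 to 44.0 ± 2.30 FPKM (log2 1.06), HSPH1 by 0.82 (log2) and the more abundant model of HSP90AA1 from 289 to 544 FPKM (0.91). HSP90AB1 stood at 939 and 959 FPKM and was not called.

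A list of acute-phase and complement genes was likewise prompted by SAA1, HP, C1R, C1S, CFB and C3. Of the 9 tested models of its other members, 3 were lower, 0 higher and 6 not called, with a median log2 change of -0.17 (camera of limma p = 0.00858, p = 0.0704 with an estimated correlation). Among them were A2M (1.31 to 0.120 FPKM, log2 -1.05) and LCN2 (1.84 to 0.683 FPKM, -0.74). Both p-values are of lists made on these data, and neither held at 0.05 with an estimated correlation.

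The rise of FABP4 was far beyond that of other fat cell genes. The median log2 change of the other tested adipocyte members was 0.35 against 5.82 for FABP4, which argues against a rise of that whole group by a like amount. The largest log2 change among tested models within 3 positions of FABP4 was -0.59, in CCN3. A model on the other side of FABP4 also fell by 0.59. Positions follow the numbers in the model identifiers, and the distances are unknown. The values thus argue only against activation that reaches these models. A candidate explanation that stays open is that reads of the transduced lncFABP4 were counted on the FABP4 model: 0 models of the table carry the name of the lncRNA, and the values cannot be told apart from a rise of the messenger RNA. For ZNF281, a single tested model lies within 3 positions, DDX59 at a log2 change of 0.0151 and on 1 side only, so activation of the region stays open there, as do reads from the vector counted on the ZNF281 model, which no value here tests.

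Of 11064 models, 2958 were called with the real split, and the highest count of the other splits was 1. Each other split puts samples of both groups together, so a difference between the groups widens the spread there and keeps calls low. The low counts therefore do not show how many calls chance alone would give. As many as 2958 came from 1 of 10 splits, and 10 splits are too few for a share under 0.05. A shift of all other values by the share that FABP4 takes is argued against as the cause of that number, since 3000 models were called after rescaling without FABP4. Without lncFABP4 replicate 1, 3468 models were called, more than the 2958 with all samples, although fewer samples lower the count by themselves. That library thus held the number down. Its Pearson's r with the EGFP samples was 0.973 to 0.977, against 0.966 to 0.972 for lncFABP4 replicates 2 and 3. Whether lncFABP4 replicate 2 or 3 weighs on the number stays open, with 1815 and 1673 called without each. Differences between the viral preparations, such as dose, go with the groups in this design and stay open.

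The rise of chaperone genes may reflect a heat-shock response that differed between the groups, a hypothesis from the same data. The members outside the prompting genes gave p = 2.69e-08 with the preset correlation and p = 0.0803 with an estimated correlation, so it stays open. A different interferon response to the 2 viruses also stays open. The interferon list had an adjusted p of 0.246 with camera, which does not exclude a difference. No value here ties such a response to the chaperone genes, so that list does not test their rise.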
